A study of Arabidopsis thaliana with 24 samples.

How the data were processed

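Biotin-labelled RNA from true leaves was hybridised to Affymetrix Arabidopsis arrays, 24 in all, 1 per sample. The values deposited by the authors are log2 expression values of 22810 probe sets. The submitters' processing notes name RMA, with no version, which corrects the background, normalizes between arrays by quantiles and summarises probes on the log2 scale. The log base is taken from RMA and is not stated in the values themselves. Each probe set had also been centred on its own median over the 24 arrays, since the largest absolute median was 5e-07, and the largest span of 1 probe set over the arrays was 8.98. Centring removes the expression level, so no probe set could be called dim or bright, and signal over background is not known here. It leaves differences between groups unchanged. Array medians lay between -0.035 and 0.033. The 64 array control probe sets were left out and 22746 were tested.

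Groups were taken from the labels for treatment, time of treatment and time after treatment, as deposited, with 3 arrays in each of 8 groups. No sample was moved to another group at any step. Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 24 arrays with a mean per group, so that the groups share an estimate of the spread (16 residual and 4.03 prior degrees of freedom). Each contrast was tested with the moderated statistic of limma, with 2-sided p values and Benjamini-Hochberg adjustment over all probe sets of the contrast, at an adjusted p of 0.05. The planned contrasts were SA against water at 0 h and 3 h for each time of treatment, the difference of the 3 h effects between the times, 3 h against 0 h in water, and ZT24 against ZT36 in water. Contrasts against the arrays labelled SA 0 h, and the difference of the 0 h effects between the times, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

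The platform table listed 1 gene symbol for 13513 probe sets and several for 503, and 8730 tested probe sets are unnamed here. Symbols were updated through gene identifiers in a RefSeq table of the TAIR10.1 assembly, which matched 13436 of the probe sets with 1 symbol. It was used for names and no coordinates are given, because no genome build applies to these values in the sources used here. For each gene the probe set with a plain name ending and the lowest identifier was kept (13286 genes), in place of the planned choice by highest mean, which centred values do not hold. Probe sets of closely related genes may share signal.

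Most genes named in the text followed a rule written before the data were examined: per contrast the 8 largest rises and 8 largest falls that passed the test, with groups that did not overlap (4 and 4 for the 0 h and water contrasts, and the test alone for differences of effects), and up to 4 called members per gene list. The text gives a selection of these, in some cases with their values in further contrasts. The rule was applied also to the contrasts against SA 0 h, which were added after the data were seen. The members named from the ATG, SEC and VPS, WRKY and UDP-glycosyltransferase families, other than WRKY53, UGT76B1, UGT73C1 and UGT74F1, and BSMT1, which was not called, fall outside the rule and were chosen after their values were seen. They were not included when calls of named genes were recomputed under the alternatives. A further 7 genes that the rule always names had no named probe set and are not analysed here. Of 268 entries in 18 lists fixed beforehand, 30 had a named probe set, and 5 lists had at least 3 measured members and were tested. A further 28 families of at least 5 members, matched by symbol, were tested with them, 33 lists in each contrast. They were fixed after the counts of called probe sets were known and before the values of any gene were. The test was limma's camera with a preset correlation of 0.01, with an estimated correlation beside it, adjusted over the 33 lists.

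The fit was tested on simulated data with 200 changed probe sets among 22746. For the SA effect at ZT24 and 3 h, 73.1% of changes of 0.5 and 98.5% of changes of 1 on the log2 scale were recovered, and for the difference between the times 37.3% and 88.1%. For water at 3 h against 0 h after ZT24 the shares were 68.7% and 95.5%. Alternatives were a second normalization (array median centring and quantiles), a fit of the arrays compared alone, a trended and robust prior, array weights, 1 probe set per gene, an added absolute log2 fold of at least 1, a block on runs of title numbers, subtraction of the 0 h groups, and each array left out in turn. A filter on probe sets of low mean was planned and could not be run on centred values, and leaving out those with the lowest SD was added in its place after the data were seen. The rule for 1 probe set per gene was likewise settled after the values were found to be centred. The second normalization also acted on centred values, so it gave every array the same distribution of deviations. Array SDs ran from 0.29 in SA 0 h to 0.65 in SA 3 h, so calls lost or gained under it may come from that step.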

Results

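Transcript levels were measured on Affymetrix arrays in true leaves of wild-type Arabidopsis thaliana, to ask how the response to salicylic acid (SA), a plant immune hormone, depends on the time at which it is given. Plants 23 days old, raised with a 12 h day length, had spent 24 h in constant light when they received water or 1 mM SA. Treatment was given at ZT24 or ZT36 (hours on the zeitgeber clock), and leaves are labelled as taken 0 h or 3 h after treatment. The 8 groups held 3 arrays each, 24 in all, described by the labels as biological replicates. Values are log2 expression relative to the median of each probe set over the 24 arrays, so they carry differences between samples and no absolute level. Arrays of one group correlated with each other at r of 0.62 to 0.94 across probe sets, which are not independent replicates, and the number of arrays limits the precision. Errors on log2 differences are standard errors (SE) from limma with n = 3 arrays per group, and adjusted p values are from limma with Benjamini-Hochberg adjustment over 22746 probe sets.

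GI (AT1G22770), an evening-phased clock gene, was lower at ZT24 than at ZT36 in the arrays labelled water 0 h, by -4.10 ± 0.20 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 1.5e-12). COR27 (AT5G42900), a cold-regulated gene under clock control, differed by -6.21 ± 0.22, AT4G33980 by -6.14 ± 0.12 and AT1G56300, which encodes a DnaJ-domain protein, by -6.51 ± 0.23. In the other direction, HYH (AT3G17609), a light-signalling bZIP factor, was higher at ZT24 by 4.43 ± 0.16, TBL26 (AT4G01080) by 4.83 ± 0.32 and AT2G27420, a cysteine proteinase family gene, by 5.96 ± 0.24. In all, 9311 probe sets differed between the times of treatment at 0 h, 4253 higher and 5058 lower at ZT24. In the arrays labelled water 3 h, 8658 differed, 3827 higher and 4831 lower, and GI stood at -4.18 ± 0.20 and HYH at 4.28 ± 0.16. Both comparisons called 6960 probe sets together, 6955 of them with the same sign, and their log2 differences correlated across probe sets at r = 0.94 although no array is shared.

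All 11 measured members of the autophagy family ATG were lower at ZT24 than at ZT36 in the water 0 h arrays, with a median of -0.97 (camera adjusted p = 2.2e-06 with a preset correlation, and adjusted p = 0.23 with an estimated correlation). ATG8B differed by -1.54 and ATG8E by -1.42. Of the 23 TBL genes, a family of wall polysaccharide acetylation proteins, 13 were higher and 2 lower at ZT24 (camera adjusted p = 0.00084, and adjusted p = 0.12 with an estimated correlation). All 3 measured genes of the redox list were higher at ZT24, among them glutathione reductases GR1 (AT3G24170) by 2.26 ± 0.10 and GR (AT3G54660) by 1.80 ± 0.14 (camera adjusted p = 0.0012, and adjusted p = 0.18 with an estimated correlation).

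Little separated the arrays labelled water 3 h from those labelled water 0 h. After ZT24, limma with Benjamini-Hochberg adjustment called 0 probe sets, with 728 at an unadjusted p under 0.05, and GI differed by -0.17 ± 0.20 and HYH by -0.07 ± 0.16. After ZT36 it called 2, with 3049 at an unadjusted p under 0.05, and GI differed by -0.09 ± 0.20 and HYH by 0.07 ± 0.16. One of the pair, AT2G41980, rose by 0.53 ± 0.08 (adjusted p = 0.03), and the other has no gene name here. The AT2G41980 call was lost without water ZT36 3h replicate 1 (adjusted p = 0.27), water ZT36 3h replicate 2 (0.073) or water ZT36 0h replicate 3 (0.29), after quantile normalization (0.11) and with only the arrays compared (0.39). Single arrays moved the ZT36 count widely: it was 705 without water ZT36 0h replicate 1, 138 without water ZT36 3h replicate 3, 4 without water ZT36 0h replicate 2 and 0 without any of the other 3 arrays, and array weights gave 1355. The groups did not overlap at 10.1% of probe sets after ZT24 and at 16.2% after ZT36, where chance gives 10%.

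The arrays labelled SA 0 h, by contrast, stood well apart from water 0 h. At ZT24, GI was higher by 1.01 ± 0.20 (limma, Benjamini-Hochberg adjusted p = 0.0015), AT5G47330 by 3.99 ± 0.36 and AT3G15450 by 3.13 ± 0.39, while AT2G27420 was lower by -3.17 ± 0.24 and TBL26 by -2.27 ± 0.32. At ZT36, GI was lower by -2.68 ± 0.20 (adjusted p = 2.2e-08), the leucine catabolism gene MCCA (AT1G03090) by -3.48 ± 0.30, the dehydrin LTI30 (AT3G50970) by -3.83 ± 0.68 and EXLA1 (AT3G45970), an expansin-like gene, by -3.67 ± 0.34, while HYH was higher by 2.70 ± 0.16 and AT5G47330 by 3.09 ± 0.36. UGT76B1 (AT3G11340), which encodes an SA glucosyltransferase, differed by 0.14 ± 0.13 at ZT24 and -0.12 ± 0.13 at ZT36, and GRX480 (AT1G28480), an SA-induced glutaredoxin, by -0.21 ± 0.13 and 0.01 ± 0.13, none of which passed the test.

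The 0 h comparison called 3688 probe sets at ZT24, 1879 higher and 1809 lower, and 6603 at ZT36, 3442 higher and 3161 lower. Of the 1918 called at both times, 688 had the same sign and 1230 the opposite one. Those with the same sign were 527 higher and 161 lower, where independent lists would share 284 and 251. The SA 0 h difference itself differed between the times at 5949 probe sets. Because the arrays labelled water 3 h lay near water 0 h and those labelled SA 0 h did not, the counts and most of the gene values at 3 h are given against both sets of arrays. The comparisons against SA 0 h, and the test of the 0 h difference between the times, were chosen after the data were seen.

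**Figure D1:**
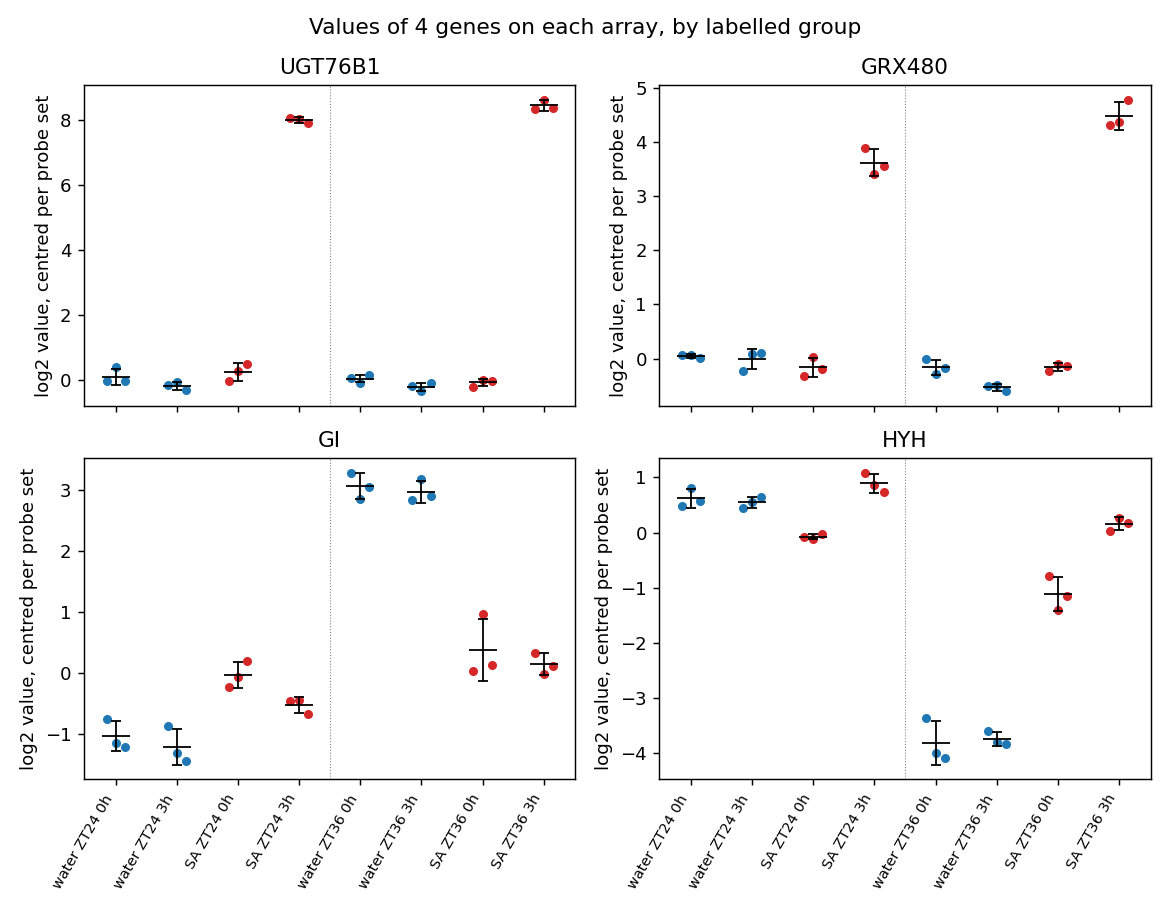
Log2 values of UGT76B1, GRX480, GI and HYH on each of the 24 arrays, centred on the median of each probe set, by labelled group on the horizontal axis; points are arrays (water blue, SA red), bars the mean ± SD of 3. UGT76B1 and GRX480 are high in the arrays labelled SA 3 h alone among the 8 groups, while GI and HYH in the arrays labelled water 3 h lie at the level of water 0 h.

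At 3 h after treatment at ZT24, UGT76B1 was higher in the SA arrays than in the arrays labelled water 3 h by 8.18 ± 0.13, a 290-fold difference (limma, Benjamini-Hochberg adjusted p = 4.1e-20), and against the arrays labelled SA 0 h by 7.75 ± 0.13. Among the other large rises were AT1G52200 (5.14 ± 0.22), a methyltransferase family gene AT4G22530 (4.94 ± 0.29), a fructokinase-like gene AT5G51830 (4.80 ± 0.28), the calmodulin-like gene AT3G01830 (4.64 ± 0.47) and the VQ-motif gene AT1G78410 (4.47 ± 0.16). With SA 0 h as control these stood at 2.63, 4.09, 4.05, 5.05 and 4.40. STOMAGEN (AT4G12970), a peptide gene that promotes stomatal formation, fell by 3.40 on the log2 scale (SE 0.35), and stood at -2.68 ± 0.35 against SA 0 h. AT2G27420 differed by -5.14 ± 0.24, AT1G29660 by -3.93 ± 0.21 and TBL26 by -3.87 ± 0.32. With SA 0 h as control these were smaller, at -2.31, -2.48 and -1.63, and AT2G27420 and TBL26 are among the genes that were higher at ZT24 than ZT36 in water.

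Of the lists fixed before the data were examined, both measured SA response genes rose at ZT24, GRX480 by 3.63 ± 0.13 and the transcription factor gene WRKY53 (AT4G23810) by 3.39 ± 0.29. Of 4 genes of SA synthesis and metabolism, UGT76B1 and SAG101 (0.99 ± 0.16) rose, while BSMT1 (-0.30) and UGT74F1 (0.21) did not pass (camera adjusted p = 0.051, and adjusted p = 0.19 with an estimated correlation). The synthesis gene ICS1, also on this list, had no named probe set, so a change in SA synthesis cannot be read from the list. Both ER genes rose, the chaperone gene ATERDJ3B (AT3G62600) by 2.56 ± 0.21 and BZIP60 (AT1G42990), of the unfolded protein response, by 0.91 ± 0.11. Both pattern recognition genes rose, the receptor gene EFR by 1.90 ± 0.15 and BIK1 by 1.17 ± 0.15. Of 4 detoxification genes, AT2G04070 rose by 1.32 ± 0.19. UGT73C1 also passed, at 0.74 ± 0.25 (adjusted p = 0.024), a call lost without SA ZT24 3h replicate 1 (adjusted p = 0.11), SA ZT24 3h replicate 2 (adjusted p = 0.11) or water ZT24 3h replicate 2 (adjusted p = 0.097), after quantile normalization (log2 0.53, adjusted p = 0.097) and against SA 0 h (log2 0.57, adjusted p = 0.099). Of 3 auxin genes, GH3.3, which encodes an auxin-conjugating enzyme, rose by 3.47 ± 0.37. STZ, a zinc-finger gene of the touch and wound list, rose by 1.22 ± 0.24, a call lost after quantile normalization (0.39, adjusted p = 0.22). GI rose by 0.68 ± 0.20 against water 3 h, a call lost without water ZT24 3h replicate 3 (0.56, adjusted p = 0.059), and stood at -0.50 ± 0.20 against SA 0 h (adjusted p = 0.068). One of 3 redox genes, GR, was lower (-0.47 ± 0.14, and -0.30 with adjusted p = 0.12 against SA 0 h), as was the guard cell gene FMA (-0.44 ± 0.11, and -0.31 with adjusted p = 0.081 after quantile normalization), while 0 of 3 photosynthesis, 0 of 2 jasmonate and 0 of 2 root genes passed. Adjusted over the list alone and against water 3 h, the counts were 2 of 2 SA response, 2 of 4 SA synthesis and metabolism, 2 of 2 ER, 2 of 2 pattern recognition, 2 of 4 detoxification, 1 of 3 auxin, 1 of 3 redox and 0 of 3 photosynthesis genes.

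STZ rose by 2.73 ± 0.24 at ZT24 with SA 0 h as control (limma, Benjamini-Hochberg adjusted p = 1.4e-08), beside 1.22 against water 3 h, and BZIP60 rose by 1.21, SAG101 by 1.09, GRX480 by 3.77 and AT2G04070 by 1.37. WRKY53 rose by 2.98 there, ATERDJ3B by 2.08, BIK1 by 0.85 and GH3.3 by 2.41, and EFR rose 2.82-fold. IAA29 stood at -0.14 against water 3 h and at -1.06 ± 0.35 against SA 0 h (adjusted p = 0.022). That call was lost after quantile normalization (0.056) and without SA ZT24 3h replicate 1 (0.077) or 2 (0.055) or SA ZT24 0h replicate 2 (0.093) or 3 (0.063). FMA stood at -0.31 ± 0.11 (adjusted p = 0.046), lost after quantile normalization (0.65), with only the arrays compared (0.16) and without SA ZT24 0h replicate 1 (0.19) or 3 (0.15) or SA ZT24 3h replicate 2 (0.23).

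Of 26 membrane trafficking genes of the SEC and VPS families, 15 were higher, 3 lower and 8 not called at ZT24 against water 3 h (camera adjusted p = 0.0096, and adjusted p = 0.27 with an estimated correlation). VPS60.1 rose by 1.81, VPS20.1 by 1.26 and KEU, a syntaxin-binding protein gene, by 1.18, and against SA 0 h by 1.45, 1.19 and 1.17. With SA 0 h as control, 12 were higher and 3 lower (camera adjusted p = 0.0054, and adjusted p = 0.33 with an estimated correlation), and the family was among 2 lists called there with the preset correlation. Of 7 WRKY genes, 3 rose, WRKY53, WRKY6 (2.08, and 1.97 against SA 0 h) and WRKY47 (0.62, and 0.32 with adjusted p = 0.15 against SA 0 h), and the family missed the threshold (camera adjusted p = 0.052). These families were fixed after the counts of called probe sets had been seen and before the values of any gene were, and the members given as examples were chosen after their values were seen.

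Across the array, 8677 probe sets differed at ZT24 against water 3 h, 4017 higher and 4660 lower, and 7211 against SA 0 h, 3248 higher and 3963 lower. Both controls called 5757 with the same sign. Independent lists would share 574 higher and 812 lower, against 2772 and 2985 observed. The log2 differences against the 2 controls correlated across probe sets at r = 0.87 (covariance 0.345), where simulated unchanged groups gave 0.50 (covariance 0.011). The simulated groups shared the SA 3 h arrays in the same way, so array noise shared by the comparisons gave only that covariance of 0.011. Part of the excess of shared calls over independent lists may still come from the shared SA 3 h arrays, since 3 arrays cannot be split.

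At 3 h after treatment at ZT36, UGT76B1 rose by 8.66 ± 0.13 against water 3 h, a 403-fold difference (limma, Benjamini-Hochberg adjusted p = 1.3e-20), and by 8.52 ± 0.13 against SA 0 h. AT5G03350, a legume lectin family gene, rose by 8.32 ± 0.38 against water 3 h and by 5.04 ± 0.38 against SA 0 h. GRX480 rose by 5.01 ± 0.13, AT5G52760, which encodes a heavy-metal-associated domain protein, by 5.42 ± 0.76, AT1G13470 by 5.17 ± 0.40, a chitinase family gene AT4G01700 by 5.15 ± 0.25 and AT2G39210 by 5.00 ± 0.25. The values with SA 0 h as control were 4.63, 4.47, 4.62, 2.96 and 3.22. EXPA8 (AT2G40610), an expansin gene for wall loosening, fell by 3.27 on the log2 scale (SE 0.35), with -2.45 ± 0.35 against SA 0 h, and STOMAGEN stood at -2.83 ± 0.35 and -2.65 ± 0.35. Other falls against water 3 h were not seen against SA 0 h: AT3G28310 went from -3.79 ± 0.15 to -0.28 ± 0.15 and MCCA from -3.12 ± 0.30 to -0.39 ± 0.30.

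Of the fixed lists at ZT36, WRKY53 rose by 3.89 ± 0.29 beside GRX480. UGT76B1, SAG101 (0.59 ± 0.16, a call lost after quantile normalization with adjusted p = 0.065) and UGT74F1 (0.36 ± 0.10) rose among the 4 genes of SA synthesis and metabolism. This list had a camera adjusted p = 0.041, and adjusted p = 0.16 with an estimated correlation, and without SA ZT36 3h replicate 1 no list was called. With SA 0 h as control this list had a camera adjusted p = 0.0024, and adjusted p = 0.032 with an estimated correlation. UGT76B1 was by far its largest member there (8.52, beside 0.79 for SAG101, 0.35 for UGT74F1 and 0.90 for BSMT1, which was not called). ICS1 had no named probe set, so a change in SA synthesis cannot be read from the list here either. ATERDJ3B rose 11.3-fold, and by 2.65 ± 0.21 on the log2 scale against SA 0 h. BZIP60 rose by 0.69 ± 0.11, EFR by 1.74 ± 0.15 and STZ by 2.60 ± 0.24, while BIK1 did not pass (0.19 ± 0.15). AT2G04070 rose by 0.72 ± 0.19. UGT73C1 also passed, at 0.68 ± 0.25 (adjusted p = 0.034), a call lost without SA ZT36 3h replicate 1 (adjusted p = 0.08) or 2 (log2 0.42, adjusted p = 0.23) or water ZT36 3h replicate 2 (adjusted p = 0.086) or 3 (adjusted p = 0.091), after quantile normalization (log2 0.55, adjusted p = 0.078) and against SA 0 h (log2 0.56, adjusted p = 0.11). GH3.3 rose by 2.56 ± 0.37 and IAA29, an auxin-response repressor gene, differed by -2.59 ± 0.35, with -1.24 ± 0.35 against SA 0 h (-0.99 with adjusted p = 0.063 without SA ZT36 3h replicate 2). GI differed by -2.83 ± 0.20 against water 3 h and -0.23 ± 0.20 against SA 0 h, and GR1 by 1.05 ± 0.10 and 0.04 ± 0.10. Of 3 photosynthesis genes, the antenna protein genes LHCB4.2 (-1.04 ± 0.12) and LHCB4.1 (-0.40 ± 0.08) were lower, FMA was lower by -0.48 ± 0.11, and 0 of 2 jasmonate and 0 of 2 root genes passed. Adjusted over the list alone and against water 3 h, 3 of 4 SA synthesis and metabolism, 2 of 4 detoxification, 3 of 3 auxin, 1 of 3 redox and 2 of 3 photosynthesis genes passed.

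WRKY53 rose by 2.42 ± 0.29 at ZT36 with SA 0 h as control (limma, Benjamini-Hochberg adjusted p = 1.2e-06), beside 3.89 against water 3 h. STZ rose by 2.54, GH3.3 by 2.49, EFR by 1.74, SAG101 by 0.79 and BZIP60 by 0.78, while BIK1 did not pass (0.35, adjusted p = 0.093). AT2G04070 rose by 0.64, a call lost without SA ZT36 3h replicate 2 (adjusted p = 0.059), and UGT74F1 by 0.35, a call lost without SA ZT36 0h replicate 1 (0.059). LHCB4.2 stood at -0.65 ± 0.12, and at 0.04 after quantile normalization (adjusted p = 0.89). LHCB4.1 stood at -0.23 ± 0.08, a call lost after quantile normalization (-0.11, adjusted p = 0.34), with only the arrays compared (0.098) and without SA ZT36 0h replicate 2 (0.15) or 3 (0.098) or SA ZT36 3h replicate 2 (0.2). FMA stood at -0.40, lost without SA ZT36 0h replicate 2 (0.063). GR stood at -0.05 against water 3 h and -0.38 against SA 0 h (adjusted p = 0.041), lost after quantile normalization (0.64) and without any of the SA ZT36 arrays other than SA ZT36 3h replicate 1 (0.076 to 0.16).

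At ZT36, 9133 probe sets differed against water 3 h, 4210 higher and 4923 lower, and 6762 against SA 0 h, 3028 higher and 3734 lower. Both controls called 5444 with the same sign, 2584 higher and 2860 lower, where independent lists would share 560 and 808. The log2 differences against the 2 controls correlated at r = 0.86 (covariance 0.349), where simulated unchanged groups that shared arrays in the same way gave 0.50 (covariance 0.011). Part of the excess of shared calls over independent lists may come from the shared SA 3 h arrays.

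**Figure D2:**
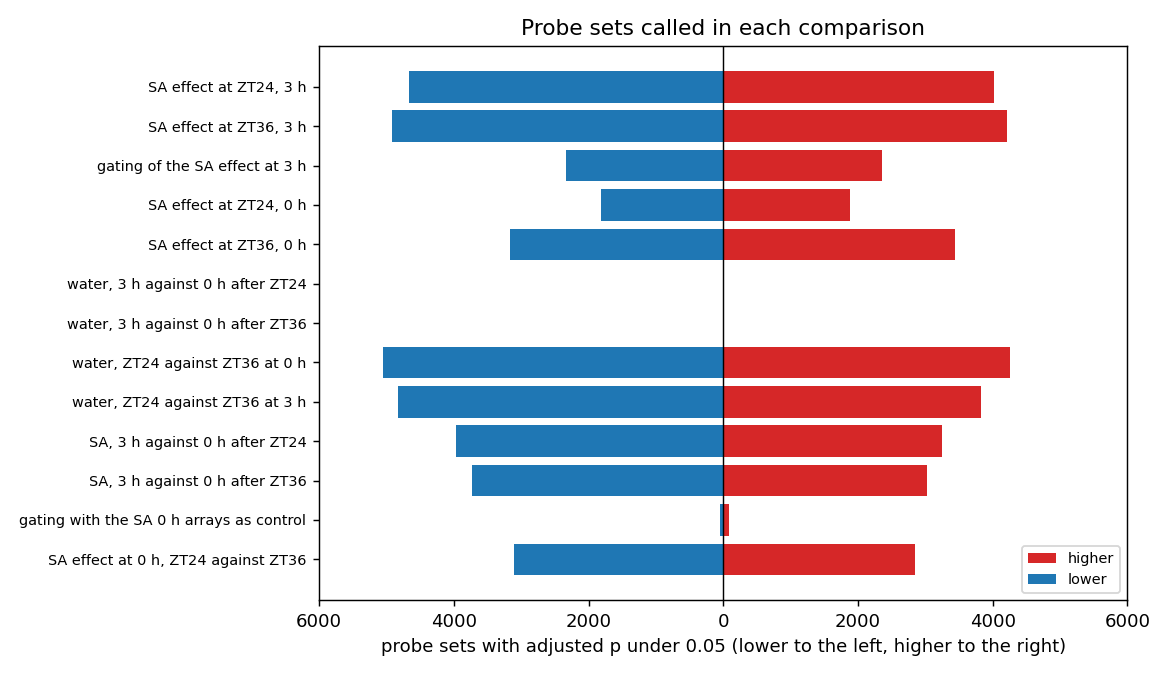
Number of probe sets with adjusted p under 0.05 in each comparison, of 22746 tested; bars to the right count probe sets higher in the first-named condition and bars to the left those lower, both from 0. The comparison of water 3 h with 0 h has 0 and 2 probe sets, and the time-of-day difference in the SA effect has 4704 against water 3 h and 136 against SA 0 h.

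UGT76B1, GRX480, WRKY53, ATERDJ3B, EFR and GH3.3 rose and STOMAGEN fell at both times of treatment, against either control. The comparisons against water 3 h called 5799 probe sets at both times, 5327 with the same sign and 472 with the opposite one. The shared calls were 2659 higher and 2668 lower, where independent lists would share 743 and 1009. Against SA 0 h, 5205 were called at both times, 5192 with the same sign and 13 with the opposite one. Across probe sets, the log2 differences at ZT24 and ZT36 correlated at r = 0.69 (Spearman 0.56) against water 3 h and r = 0.88 (Spearman 0.76) against SA 0 h, with no array shared between the times.

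AT1G51850, a leucine-rich repeat kinase gene, was among those called against both controls in a direct test of whether the SA effect differed between ZT24 and ZT36. Its rise was larger at ZT24 by 2.21 ± 0.21 against water 3 h and by 1.91 ± 0.21 against SA 0 h (limma, Benjamini-Hochberg adjusted p = 4.7e-07 and 0.00017), from 3.93 ± 0.15 at ZT24 to 1.72 ± 0.15 at ZT36 with the water control. AT3G26910 also had a more positive effect at ZT24, by 2.06 ± 0.25 and 1.56 ± 0.25. AT1G13650 fell at ZT24 by more than at ZT36, with a difference of -2.88 ± 0.20 against water 3 h and -2.32 ± 0.20 against SA 0 h (adjusted p = 6.7e-09 and 2.2e-06). AT5G44050, a MATE transporter family gene, differed by -3.44 ± 0.21 and -1.45 ± 0.21. In water 0 h both genes were higher at ZT24 than at ZT36, AT1G13650 by 3.19 ± 0.14 and AT5G44050 by 2.80 ± 0.15. AT1G13650 fell at ZT24 to a mean of -0.02 in the SA 3 h arrays, near its -0.23 in the SA 0 h arrays at ZT36. Whether its lower start at ZT36 limited the fall there cannot be told from centred values. GRX480 rose less at ZT24, by -1.39 ± 0.18 and -0.86 ± 0.18. Its call against SA 0 h was lost when only the arrays compared were fitted (adjusted p = 0.12), with a trended and robust prior (0.26), and without any SA array other than SA ZT24 0h replicate 1, SA ZT24 3h replicate 1 and SA ZT36 3h replicate 1 (adjusted p of 0.053 to 0.085). AT3G02840 and the scopoletin synthesis gene AT3G13610 had larger effects at ZT24 by 1.75 and 1.68 against SA 0 h, calls that were lost when only the arrays compared were fitted (adjusted p = 0.095 and 0.1).

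The largest time-of-day differences against water 3 h were in other genes. AT2G30600 differed by 4.49 ± 0.44, AT4G27450 by 3.76 ± 0.56, AT3G28310 by 3.71 ± 0.21, AT3G15450 by 3.66 ± 0.55, AT3G10020 by 3.64 ± 0.25 and GI by 3.51 ± 0.29. The values with SA 0 h as control were -0.47, -0.66, 0.26, -1.10, 0.08 and -0.27, and none of these 6 passed the test there. AT5G03350 went from -5.59 ± 0.53 to -1.08 ± 0.53, HYH from -3.56 ± 0.23 to -0.30 ± 0.23, AT3G15310, a pseudogene, from -4.65 ± 0.37 to -0.05 and TBL26 from -3.51 ± 0.45 to 0.51. AT3G28220 kept most of its size, from -4.10 ± 1.08 to -3.79 ± 1.08, and missed the threshold against SA 0 h (limma, Benjamini-Hochberg adjusted p = 0.14). AT2G27420 went from -5.05 ± 0.34 to -1.95 ± 0.34 and passed in both, the latter not when only the arrays compared were fitted (adjusted p = 0.055) or with a trended and robust prior (0.095). Of 11 ATG genes, 8 had a more positive SA effect at ZT24 against water 3 h (camera adjusted p = 2.6e-05, and adjusted p = 0.55 with an estimated correlation), and against SA 0 h 0 of 11 passed. SEC and VPS genes had 7 more positive and 1 less positive of 26 against water 3 h (camera adjusted p = 0.018, and adjusted p = 0.55 with an estimated correlation), and 0 of 26 passed against SA 0 h. Without water ZT24 3h replicate 1, 1 list was called in place of 2. Of the fixed lists, GR1 (-1.24), STZ (-1.38), BIK1 (0.98), IAA29 (2.45) and LHCB4.2 (1.09) were called against water 3 h and missed the threshold against SA 0 h.

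In all, 4704 probe sets differed in their SA effect between the times against water 3 h, 2363 more positive and 2341 less positive at ZT24. With both 0 h groups subtracted as baselines, 29 did, in a contrast over all 8 groups that has larger errors and whose recovery was not simulated. Against SA 0 h, 136 did, 92 more positive and 44 less positive, which became 1017 after median centring and quantile normalization and 52 without SA ZT36 3h replicate 2, 55 without SA ZT36 0h replicate 2 and 80 without SA ZT24 0h replicate 1. The probe sets called against both controls numbered 105, 96 with the same sign and 9 with the opposite one, where independent lists would share 10 more positive and 5 less positive, against 69 and 27 observed. Part of that excess may come from the shared SA 3 h arrays.

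**Figure D3:**
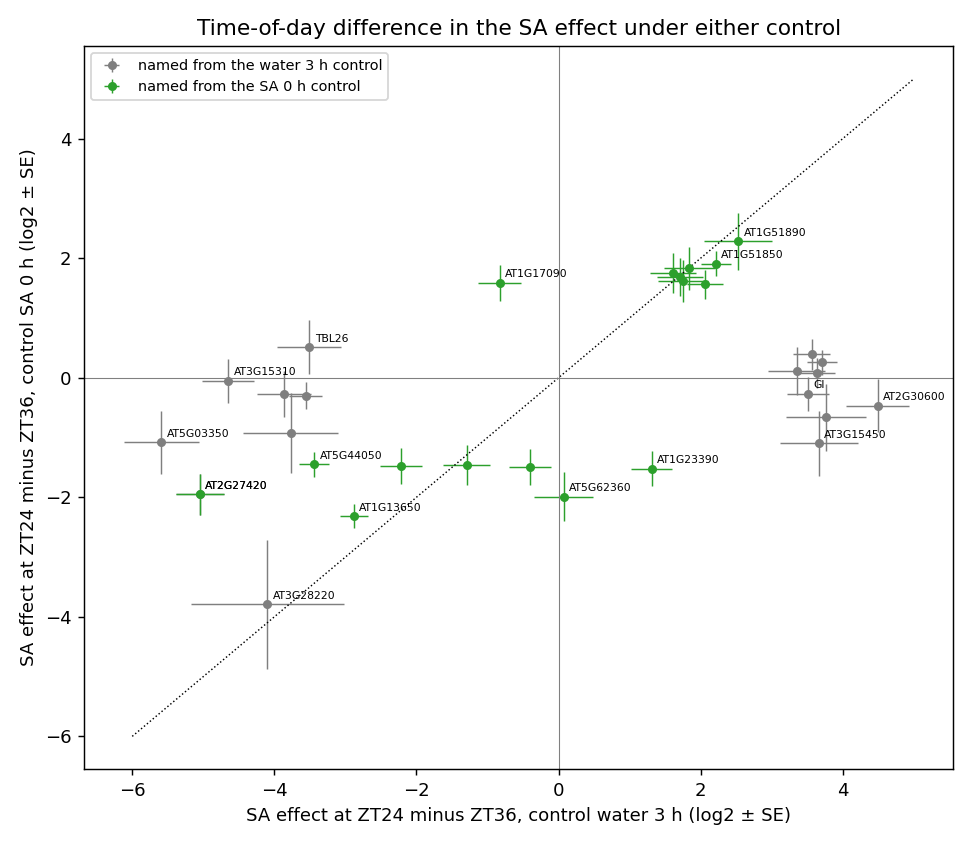
Difference in the SA effect between ZT24 and ZT36 (log2 ± SE) for the named genes with the largest differences, against the arrays labelled water 3 h on the horizontal axis and against those labelled SA 0 h on the vertical axis; grey points were named from the first, green from the second, and the dotted line marks equal values. GI lies at 3.51 and -0.27, AT1G51850 near the line at 2.21 and 1.91, and some points in crowded areas carry no name.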

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

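The test of the difference at 3 h against water was fixed before the data were examined. The tests against SA 0 h, the test of the difference at 0 h, the correlations and the counts of splits were chosen after the results they bear on had been seen. The correlations had themselves been seen in an exploratory comparison. All of these can at most argue against an explanation and cannot establish one.

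The SA effect at 3 h differed between the times of treatment at 4704 probe sets against water 3 h and 136 against SA 0 h, and the 0 h effect at 5949, each by a test of the difference itself. The same test, against water 3 h, gave a more positive SA effect at ZT24 for AT2G30600 (4.49), AT4G27450 (3.76), AT3G28310 (3.71), AT3G15450 (3.66), AT3G10020 (3.64), AT5G43440 (3.56), GI (3.51) and AT1G70820 (3.35). It gave a less positive one for AT5G03350 (-5.59), AT2G27420 (-5.05), AT3G15310 (-4.65), AT3G28220 (-4.10), AT5G19240 (-3.86), AT5G20790 (-3.77), HYH (-3.56) and TBL26 (-3.51).

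Arrays labelled water 3 h lay near water 0 h, while arrays labelled SA 0 h stood apart from it. The labels as deposited, with clock time passing in the water 3 h arrays, would have these move along the difference between ZT24 and ZT36. Their change correlated with that difference at 0.06 after ZT24 and -0.22 after ZT36, neither in the direction that 3 h of clock time would give. The difference was taken from the arrays labelled SA 0 h, whose labels are themselves in doubt. The water change was also small, which weakens its correlation as a test of direction. SA acting before the 0 h harvest as it does at 3 h would make the SA 0 h difference resemble the SA response from other arrays, but these correlated at 0.05 and -0.02. A candidate explanation is that the labels of the water 3 h and SA 0 h arrays were exchanged. The SA 0 h difference moved along the clock difference at -0.43 after ZT24 and 0.54 after ZT36, the directions this predicts. Those signs were partly built in, because the subtracted water 0 h arrays had nearly the clock difference of water 3 h (r = 0.94). Any SA 0 h arrays with a smaller clock difference would give them, so they cannot single out exchanged labels. A rapid effect of SA on clock-phased genes, unlike its effect at 3 h, stays open and untested for the SA 0 h arrays. It would not account for the small water change, with 0 and 2 probe sets called beside 9311 between the times in water 0 h. Exchanged labels would bear on both parts of the pattern. The unsteady counts of the ZT36 water comparison (0 to 705 with 1 array left out) also stay open, and the labels were kept as deposited.

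The time-of-day difference in the SA effect was large against water 3 h and small against SA 0 h. Clock time between the control and the treated arrays may account for part of the larger count, but this stays open. The difference at 3 h correlated at 0.79 with the difference in the 0 h effect. The latter comes from other arrays but was known when the test was chosen. Both subtract the ZT24 minus ZT36 difference in water, which was nearly the same at 0 h and 3 h (r = 0.94 across probe sets). A high correlation was therefore largely built in and cannot decide the question. A response to SA that truly differs with the time of treatment might show against both controls. With the same sign, 2% of the 4704 probe sets did, and these were 96 of the 136 called against SA 0 h. Clock time in 1 of the controls could mask or reverse such a difference, so it need not show against both. Since missing a threshold also does not show that effects are equal, this cannot be told apart for the rest. The count against SA 0 h also rose from 136 to 1017 after quantile normalization. That step gave the same distribution to centred arrays whose SD was 0.55 to 0.65 in SA 3 h and 0.29 to 0.36 in SA 0 h. It can shrink or stretch real differences, so it cannot tell which count is nearer, and the size stays unsettled. Both comparisons share the SA 3 h arrays, and across probe sets their covariance was 0.054 (0.022 in simulated unchanged groups) and their correlation 0.35 (0.50).

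For differences of effects, the real split was compared with 99 others, made by exchanging between the times, within each treatment, what remained after the effects of treatment and time had been removed. The real split was the 1 of 100 with as many calls against water 3 h (4704, highest other 1856), against SA 0 h (136, highest other 29) and at 0 h (5949, highest other 2660). Chance is thus unlikely as the whole source of these counts, though 1 of 100 is the smallest share the test can give. What was exchanged still held any real difference, which can lower the other counts, so these are not counts expected without one. The size of the counts stays open: the count against SA 0 h was 52 without SA ZT36 3h replicate 2, 55 without SA ZT36 0h replicate 2 and 80 without SA ZT24 0h replicate 1.

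With 3 arrays against 3, 10 splits are too few to exclude chance. The real split and the highest other gave 8677 and 0 for SA at ZT24 and 3 h, 9133 and 1 at ZT36, 3688 and 0 for SA at ZT24 and 0 h, 6603 and 1 at ZT36, 9311 and 3 for water between the times at 0 h, and 8658 and 2 at 3 h. SA 3 h against 0 h gave 7211 and 119 after ZT24 and 6762 and 0 after ZT36. In each of these 1 split gave as many. For water 3 h against 0 h, all 10 gave as many after ZT24 (0 and 45) and 3 after ZT36 (2 and 1108), where the larger count of another split points to a structure among those 6 arrays that their labels do not follow.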

How the results depend on the processing

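The control of SA 0 h arrays, the leaving out of the third of probe sets with the lowest SD and the rule for 1 probe set per gene were chosen after the data were seen, and the other alternatives before the data were examined. The rule for naming genes was fixed beforehand, and was applied also to the contrasts against SA 0 h, which were added after the data were seen. Of 236 calls of genes named by it, 218 held after median centring and quantile normalization and 231 with array weights. With a trended and robust prior 229 held, with only the arrays compared 221 and with 1 probe set per gene 236. Without the probe sets of lowest SD, 233 held and the others were not tested. Under these, 1 changed direction, LHCB4.2 in SA 3 h against 0 h after ZT36 after quantile normalization (0.04). With 1 array left out, 1518 held, 150 missed the threshold and 0 changed direction. The filter on low mean was not run. The cause of the changes below was not tested unless stated, and signal over background cannot be judged from centred values.

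Quantile normalization called 5 probe sets for water 3 h against 0 h after ZT24 and 1 after ZT36. It called 1017 for the time-of-day difference against SA 0 h (542 more and 475 less positive). It gave centred arrays of unlike spread the same distribution, so calls gained or lost under it may come from that step. Array weights gave 7 and 1355 for water. With only the arrays compared, water after ZT36 gave 0 and the difference against SA 0 h 89.

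Testing 1 probe set per named gene lowers counts because fewer are tested: SA at 3 h gave 4631 at ZT24 and 4898 at ZT36 (3083 in both), their difference 2462, SA at 0 h 2021 and 3537, water between the times 4979 at 0 h and 4575 at 3 h, water after ZT36 1, SA 3 h against 0 h 3851 and 3574, and the difference against SA 0 h 69. Adding an absolute log2 fold of at least 1 gave, in that order, 2314, 2520, 1299 in both, 1394, 494, 1011, 2347, 1840, 0, 1746, 1545 and 82.

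Subtracting the 0 h arrays gave 5060 probe sets for SA at ZT24, 5653 at ZT36 and 29 for their difference. The last spans all 8 groups and has larger errors, so 29 does not show that the effects are otherwise equal. The SA 0 h arrays subtracted here differed from water 0 h at 3688 probe sets at ZT24 and 6603 at ZT36, so they were no plain baseline. GI at ZT24 turned to -0.33 and MCCA at ZT36 to 0.36. The time-of-day difference turned sign for AT2G30600 (-1.29), AT4G27450 (-2.56), AT3G15450 (-2.55), AT3G10020 (-0.69), AT5G43440 (-0.13), GI (-0.19), AT3G15310 (0.15), AT5G20790 (0.11), TBL26 (0.69), GR1 (0.12) and WES1 (-0.44). With SA 0 h as control the difference was called at 136 probe sets, GI at ZT24 turned to -0.50, and the difference turned sign for AT2G30600 (-0.47), AT4G27450 (-0.66), AT3G15450 (-1.10), GI (-0.27), TBL26 (0.51), GR1 (0.06), WES1 (-0.18) and STZ (0.19). None of these turned values passed the test (adjusted p of 0.068 or more). Of genes named from the difference against SA 0 h, AT1G23390 was called with opposite signs under the 2 controls. It stood at 1.31 ± 0.29 against water 3 h and -1.52 ± 0.29 against SA 0 h (limma, Benjamini-Hochberg adjusted p = 0.0027 and 0.019). These 2 alternatives applied to 87 of the named-gene calls: 24 missed the threshold and 13 turned with the 0 h arrays subtracted (37 in all), and 22 and 9 with SA 0 h as control (31 in all).

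With an estimated correlation in camera, 0 lists were called for SA at ZT24, SA at ZT36, their difference and SA 3 h against 0 h after ZT24. Array titles carry numbers that fall into runs, and 84 pairs of arrays of the same run correlated at -0.36 to 0.45 in their deviations from the group means, 25 of them above 0.1, so the numbers were not taken to pair arrays, which needs every pair above it. The mean was 0.05 within runs and -0.03 between them, and 15 of 24 arrays correlated best with their own run, where chance gives 8, so an effect of run stays open. As a replicate block, the run gave 11 probe sets for water after ZT36 and 2 lists for SA at ZT36, and counts elsewhere within 1.5 times.

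Leaving out each array gave 7549 to 8501 for SA at ZT24 and 8188 to 8553 at ZT36 (5313 to 5713 in both), 3850 to 4792 for their difference, 2689 to 3235 and 5225 to 6639 for SA at 0 h, 0 and 0 to 705 for water 3 h against 0 h, 8168 to 9144 and 7144 to 7939 for water between the times, 6119 to 7032 and 5681 to 6172 for SA 3 h against 0 h, and 52 to 199 for the difference against SA 0 h. Called lists ranged from 1 to 3 for SA at ZT24, 0 to 3 at ZT36, 1 to 3 for their difference, 2 throughout and 1 to 2 for SA 3 h against 0 h, and 0 to 2 for the difference against SA 0 h.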

Other observations

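The families below were chosen after the counts of called probe sets had been seen, and the members named, other than UGT76B1, after their values had been seen.

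Of 51 UDP-glycosyltransferase genes, 16 were higher and 9 lower with SA at ZT24 against water 3 h (camera adjusted p = 0.27) and 19 and 7 at ZT36 (0.083), beside 38.1% and 40.2% of all probe sets called. Against SA 0 h, 13 were higher and 9 lower at ZT24 (0.5) and 16 and 7 at ZT36 (0.098), so the family passed in none of the 4 tests. Beside UGT76B1, UGT87A2 rose by 1.51 at ZT24 and 2.53 at ZT36, UGT73B5 by 2.30 and 2.12, UGT84A3 by 1.99 and 1.35, and UGT84A4 by 1.02 at both times, with 1.83 and 1.72, 2.03 and 1.81, 1.14 and 1.37, and 1.00 and 0.66 against SA 0 h. UGT74D1 differed by -0.44 at ZT24 and 2.09 at ZT36, and by -0.33 and 0.55 against SA 0 h.

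In the water 0 h arrays, 40.9% of all probe sets differed between the times, and 3 further families were called with a preset correlation and none of them with an estimated one. Of 13 glutathione transferase genes 7 were higher at ZT24 and 0 lower (camera adjusted p = 0.014, and adjusted p = 0.12 with an estimated correlation), and of 16 ribosomal protein genes 7 were higher and 0 lower (adjusted p = 0.037, and 0.62 with an estimated correlation). Of 19 expansin genes 9 were higher and 2 lower (adjusted p = 0.048, and 0.23 with an estimated correlation).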
